A study of Mus musculus with 24 samples.

How the data were processed

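RNA from whole brains of 4-month-old mice was measured on 24 Affymetrix arrays, 1 per sample, in 4 groups of 6. Per the labels, the groups were wild type (wt), aSYN, Hsp70 and both together (aSYN/Hsp70). The labels do not spell out aSYN, which is read here as alpha-synuclein, nor do they say how the genotypes were made. Nothing in the labels says that the samples came from separate animals, so p-values measure the spread between these samples.

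The deposited values are linear intensities, 1 per probe set and array. The program that summarised the probes into probe sets is not given in the sources used here. The mean intensity of every deposited array, without the lowest and highest 2% of probe sets, was 2500, while array medians ran from 458 to 893, so each array had been scaled by a single factor and the distributions still differed. Intensities were therefore transformed as log2(intensity + 16) and quantile normalised. Log2 differences of dim probe sets are understated by the added 16. The 64 control probe sets and the 18015 probe sets with the lowest means (40%) were left out, and 27022 were tested. Of the 45101 probe sets, 34958 carried 1 gene symbol, 932 carried several and 9211 were unnamed here. Of those with 1 symbol, 34754 matched a gene table of assembly GRCm38.p6 by gene ID, and 0 symbols changed. Genes were named only from probe sets with 1 symbol. The mouse gene for alpha-synuclein had no named probe set and was not analysed here.

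Each comparison was a contrast in 1 fit of all 24 arrays with a mean per group (limma 3.58.1 in R 4.3.3, lmFit and eBayes). Adjusted p-values are Benjamini-Hochberg values from limma over the 27022 probe sets, called at 0.05. The interaction is the aSYN difference with Hsp70 minus the aSYN difference without it. Single values per array, such as list scores, were compared by exact two-sided permutation tests over the 924 splits of 6 against 6, which cannot give a p below 0.00216. Such tests were fixed in advance only for the Hsp70 genes Hspa1a and Hspa1b, and those of list scores were not. Differences on separate arrays were compared by Pearson's r across probe sets, which are not independent replicates, against 100 labellings with the real one included.

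Before the data were examined, 28 gene lists with 405 different genes were fixed, of which 28 genes had no named probe set. Lists were tested with camera (preset correlation 0.01) on the brightest probe set of each of 12929 genes, with adjustment over the 28 lists within a comparison, and again with an estimated correlation. The naming rule was fixed then too. It took the 12 genes with the largest change in each direction among those called, the 5 smallest p-values where fewer than 5 genes were called, the Hsp70 genes Hspa1a and Hspa1b always, and up to 4 members per list that passed 0.05 adjusted over the list alone. Genes outside this rule are marked as chosen after their values were seen.

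The fit was tested on simulated arrays with the real means and spreads, for aSYN/Hsp70 versus aSYN over 27022 probe sets. Of 200 changed probe sets, 24% were recovered at a log2 change of 0.5 and 58% at 1, with 3 false calls, and 0 calls were made when nothing had been changed. In the step on 12929 genes the changed list was found and 0 other lists were called. The simulated probe sets were independent of each other and had the same spread in every array. Correlated genes and outlying arrays were thus absent, and these counts do not measure false calls from either in the real arrays.

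Alternatives fixed in advance were the values without quantile normalisation, an offset of 1, no filter on dim probe sets, only the arrays of the groups compared, the replicate number as a block, limma array weights, a continuous sex covariate, a trended and robust variance, and each array left out in turn. For lists, the mean over all probe sets of a gene was also tried, and the variance was trended but not robust, as camera has no robust fit. After seeing the data, fits without 4 arrays of weight under 0.5, with array weights and the sex covariate together, and with an offset of 256 were added, and called lists were tested with each array left out. The sex covariate was the mean log2 intensity of Y-linked probe sets minus that of Xist. The number of arrays limits the precision of all values. Figures were drawn with matplotlib 3.10.9.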

Results

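Whole-brain RNA of 4-month-old mice was profiled in 6 wt, 6 aSYN, 6 Hsp70 and 6 aSYN/Hsp70 samples. Array medians ran from 458 to 893 intensity units. The median Spearman correlation of an array with the others lay between 0.836 and 0.939, and no 2 arrays correlated above 0.95. Apart from the rest stood 4 arrays, with limma weights of 0.124 (aSYN/Hsp70 replicate 4), 0.251 (Hsp70 replicate 3), 0.332 (Hsp70 replicate 6) and 0.394 (aSYN/Hsp70 replicate 3). Xist and Y-linked probe sets divided the arrays by sex, with 4 female samples of 6 in wt, 4 in aSYN, 3 in Hsp70 and 2 in aSYN/Hsp70.

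**Figure D1:**
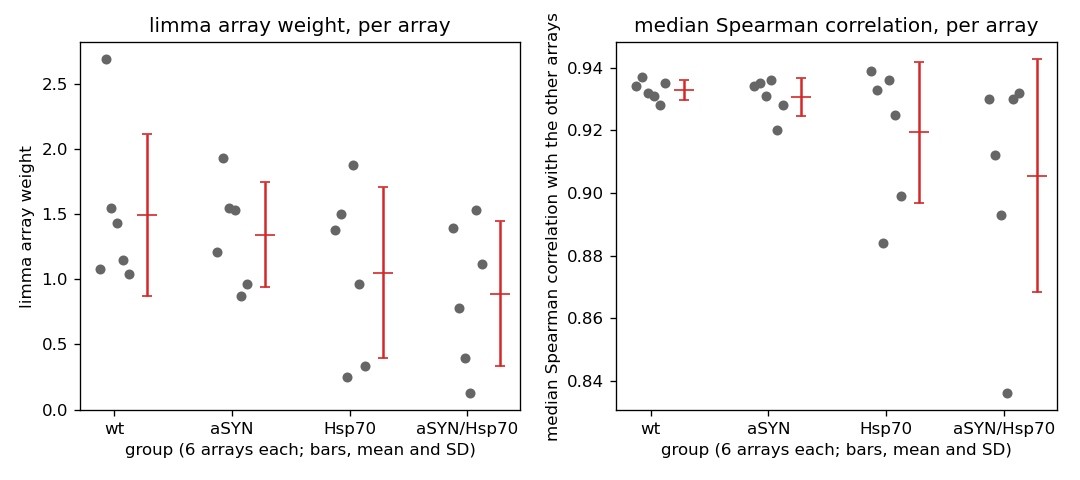
Limma array weight (left) and median Spearman correlation with the other arrays (right) for each array, by group; points are arrays and bars show the mean and SD of 6 arrays. The lowest weight, 0.124, and the lowest correlation, 0.836, belong to aSYN/Hsp70 replicate 4.

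Hspa1a and Hspa1b encode inducible HSP70 proteins, and their mouse probe sets were read first as a check of the Hsp70 label. The Hspa1a probe set averaged 10.96 ± 0.37 log2 units in wt and 10.88 ± 0.52 in Hsp70 brains (SD, n = 6, exact permutation p = 0.803). For Hspa1b, the 3 probe sets differed between Hsp70 and wt by -0.14, 0.19 and 0.26 log2 units, with exact permutation p of 0.749, 0.773 and 0.509. Between aSYN/Hsp70 and aSYN, Hspa1a differed by -0.49 and Hspa1b by 0.10, 0.60 and 0.27 (exact permutation p = 0.697, 0.732, 0.134 and 0.385). Hspa1a stood at 7.86 in aSYN/Hsp70 replicate 4, and its -0.49 turned to 0.102 without the 4 arrays that stood apart and 0.0278 with weights and the sex covariate, fits added after seeing the data. For Hspa1b, the 0.10 turned to -0.123 with the sex covariate and -0.0247 with weights and sex. The 0.19 between Hsp70 and wt turned to -0.051 with weights and sex. None of the 4 probe sets separated the samples labelled Hsp70, and mouse probes need not read a transgene of another species, so they do not check the label.

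The first question was whether the aSYN genotype alone changed the brain. Sort1, which encodes the sorting receptor sortilin, was the only call of limma: its probe set fell from 11.74 ± 0.18 in wt to 11.06 ± 0.07 in aSYN (SD, n = 6), a log2 difference of -0.68 (SE 0.10, adjusted p = 0.038). It was below the wt mean in 6 of 6 aSYN samples, which its choice from these same arrays makes likely. The next 4 genes by p did not pass, each at adjusted p = 0.0786. They were the dendritic microtubule protein Map2 (-0.70), Asb7 (-0.85), the neuronal kinesin Kif5a (-0.58) and, in the other direction, Dph5 of the diphthamide pathway (0.54). A brighter probe set of Sort1 differed by -0.13 (SE 0.08, limma adjusted p = 1) and a brighter one of Map2 by -0.04 (SE 0.10, adjusted p = 1).

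Proteasome subunits were higher in aSYN brains for 27 of 31 measured members, with a median of 0.09 log2 units (camera adjusted p = 0.000207, but adjusted p = 0.452 with an estimated correlation); 0 members passed over all probe sets or adjusted over the list alone. Interferon and MHC class I genes were higher for 11 of 15 (median 0.18, adjusted p = 0.026, and 0.464 with an estimated correlation). Heat shock and HSP70 chaperones were lower for 14 of 20 (median -0.11, adjusted p = 0.026, and 0.555 estimated), unfolded protein response genes for 13 of 15 (median -0.12, adjusted p = 0.0269, and 0.515 estimated) and astrocyte genes for 8 of 12 (median -0.08, adjusted p = 0.026, and 0.452 estimated). Striatal neuron genes were lower for 8 of 12 (median -0.05, adjusted p = 0.0331, and 0.482 estimated) and pituitary genes for 4 of 4 (median -1.27, adjusted p = 0.026, and 0.464 estimated). The pituitary score had an SD of 2.3 in wt, where replicate 5 stood at 4.03. Below the lowest wt array lay 0 of 6 aSYN arrays (exact permutation p = 0.221). Without wt replicate 5 the median was -0.612 (adjusted p = 0.288). Beside these lists, the 3' minus 5' signal of 4 control transcripts averaged 0.12 log2 units higher in aSYN than in wt (exact permutation p = 0.0887), with Pcx at 2.06 ± 0.22 against 1.72 ± 0.23 (SD, n = 6, exact permutation p = 0.026, adjusted p = 0.156 over 24 comparisons). Adjusted over the list alone, the striatal phosphodiesterase Pde10a (-0.46), the astrocyte glutamate transporter Slc1a3 (-0.26), the microglial gene Fcrls (-0.92) and the clock gene Ciart (0.84) passed, and 0 of them passed over all probe sets. The single limma call stood against 1398 probe sets at an unadjusted p under 0.05, where 1351 are expected by chance. Sort1 differed by -0.685 (SE 0.107, against -0.683, SE 0.105) with the sex covariate (adjusted p = 0.0643), by -0.683 (SE 0.112) without the dim filter (adjusted p = 0.18) and by -0.724 to -0.634 with 1 aSYN or wt array left out (adjusted p 0.03 to 0.167), where it was called in 2 of 12 fits, those without wt replicate 1 or 4, and 9 of the 12 made 0 calls; the fit of only these groups' arrays also made 0, and array weights gave 217. Of the 7 lists, 4 lost the call without quantile normalisation, 5 with array weights and, in tests added after seeing the data, 6 without the 4 arrays that stood apart, while with 1 aSYN or wt array left out the proteasome list was called in 12 of 12 fits and each other list lost the call in 2 to 6 of 12.

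Hsp70 brains were compared with wt to see what that genotype did alone. Genes of striatal projection neurons were lower for 12 of 12 measured members, with a median of -0.26 log2 units (camera adjusted p = 1.11e-08, and adjusted p = 0.0429 with an estimated correlation). Tac1, the substance P precursor, differed by -0.46 (SE 0.12), the dopamine receptor Drd1 by -0.34 (SE 0.10), the retinoic acid receptor Rarb by -0.30 (SE 0.09) and Pde10a by -0.27 (SE 0.09), and these 4 passed adjusted over the list alone. The mean striatal score per array was -0.24 ± 0.14 in Hsp70 relative to wt (SD, n = 6, exact permutation p = 0.0108, a test not fixed in advance), and 5 of 6 arrays lay below the lowest wt array. Other cell type and region lists did not pass. Oligodendrocyte and myelin genes were lower for 8 of 11 (median -0.10), thalamus genes for 7 of 8 (-0.17), astrocyte genes for 10 of 12 (-0.05) and pituitary genes for 4 of 4 (-0.90), each at adjusted p = 0.196. Hypothalamus genes were lower for 6 of 8 (-0.28, adjusted p = 0.206) and meninges genes higher for 10 of 11 (0.10, adjusted p = 0.249). The myelin list passed without the 4 arrays that stood apart, a fit added after seeing the data (adjusted p = 0.0191, from 0.0191 to 0.24 over 11 settings). The hypothalamus list passed with array weights (0.0377, from 0.0377 to 0.293). Of the single genes, 0 were called by limma, with 1305 probe sets at an unadjusted p under 0.05. The 5 smallest p-values, of Bend4 (-1.49), Yipf3 (0.47), Prss29 (2.16), Snhg10 (0.77) and Nktr (0.36), all had an adjusted p of 0.881.

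**Figure D2:**
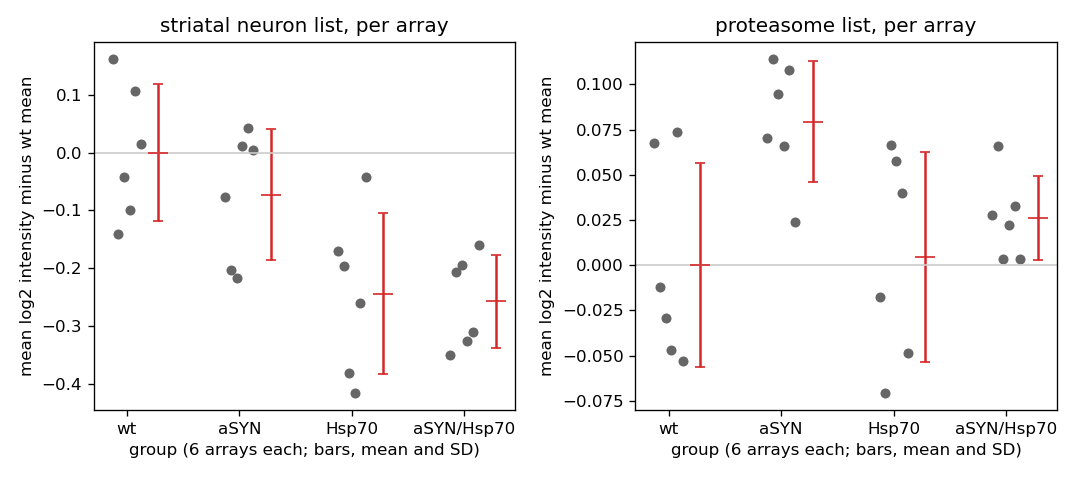
Mean log2 intensity of the striatal neuron list (left) and the proteasome list (right) per array, minus the wt mean; points are arrays and bars show the mean and SD of 6 arrays. The striatal score averaged -0.24 in Hsp70 and -0.26 in aSYN/Hsp70, and the proteasome score 0.079 in aSYN.

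Brains with both genotypes were compared with the same 6 wt arrays, so the differences from wt are not independent of those of Hsp70 brains. Striatal genes were lower for 12 of 12 members (median -0.20, camera adjusted p = 9.33e-05, and 0.366 with an estimated correlation), among them Tac1 (-0.45), the dopamine receptors Drd2 (-0.36) and Drd1 (-0.30). The striatal score was -0.26 ± 0.08 (SD, n = 6), below the lowest wt array in 6 of 6 arrays (exact permutation p = 0.00216, the smallest possible, in a test not fixed in advance). Oligodendrocyte and myelin genes were lower for 10 of 11 (median -0.22, adjusted p = 0.000889, and 0.415 estimated), with Cnp at -0.37, Mal at -0.33 and Mobp at -0.26. Thalamus genes were lower for 6 of 8 (median -0.37, adjusted p = 0.00198, and 0.415 estimated; 0.25 with the mean of all probe sets of a gene, which ended the call), with Plekhg1 at -0.51, Prkcd at -0.43, Slc17a6 at -0.40 and Rora at -0.27. The array of weight 0.124 lay lowest in its group in both the myelin (-0.744) and thalamus (-1.12) scores.

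Single genes gave 0 limma calls in this comparison, with 3922 probe sets at an unadjusted p under 0.05. Dopamine neuron genes that passed adjusted over the list alone were the vesicular monoamine transporter Slc18a2 (-0.83), the receptor Ret (-0.92) and Aldh1a1 (-0.42), while the list as a whole did not pass (lower for 6 of 9, adjusted p = 0.213, and 0.732 with an estimated correlation). It passed without the dim filter (0.0287) and, in a fit added after seeing the data, without the 4 arrays that stood apart (0.0208). Fcrls (-0.95), the choroid plexus gene Clic6 (-0.38) and the neuropeptide Nts (-0.60) passed in the same way. The smallest p-values, each at adjusted p = 0.154, were those of the G protein subunit Gnb1 (1.82), Ccdc82 (-0.79), Nbea (-0.52), the chromatin remodeller Chd4 (-1.84) and Il1f6 (1.08). The fit without the 4 arrays that stood apart gave 1 call.

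What Hsp70 added to the aSYN genotype gave the most calls. Of 194 probe sets called by limma, 134 were higher and 60 lower in aSYN/Hsp70 than in aSYN, in 115 and 47 named genes, with a median change of 0.60 log2 units. The largest increases were in 2610005L07Rik (1.42), the melanin enzyme Dct (1.32), Lacc1 (1.14), Zfp953 (1.07), the ascorbate transporter Slc23a2 (1.01) and the cannabinoid receptor Cnr1 (0.97, SE 0.15, adjusted p = 0.00606), followed by Cyria (0.94), Fndc3a (0.90), Usp12 (0.89), Endov (0.88), the lysosomal sulfatase Ids (0.88) and Mettl21a (0.87). The largest decreases were in Bop1 (-1.93), the bicarbonate transporter Slc4a8 (-1.91), endothelin 3 (Edn3, -1.28), Fgf14 (-1.16), the splicing helicase Snrnp200 (-1.12), the transcription factor Npas3 (-1.06), Adamts20 (-1.03), Tob2 (-1.03), mitochondrial Ssbp1 (-1.01), Glipr1 (-1), Slc18a2 (-0.85, SE 0.18, adjusted p = 0.0281) and Rorb (-0.82). Each of these 24 differed from the aSYN mean in its direction in 6 of 6 aSYN/Hsp70 arrays, which their choice from these same arrays makes likely. Several of the largest changes were in dim probe sets. Mean log2 intensities in aSYN and aSYN/Hsp70 were 8.74 and 6.81 for Bop1 and 8.66 and 6.76 for Slc4a8. They were 7.47 and 8.9 for 2610005L07Rik and 8.2 and 9.52 for Dct. Brighter ones were Ssbp1 (13.17 and 12.16) and Cyria (11.17 and 12.11).

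Other probe sets of the same genes often did not move with them. The brighter Cnr1 probe set differed by -0.43 (SE 0.18, limma adjusted p = 0.2) and the brightest of Ids by -0.03 (SE 0.09, adjusted p = 0.88), while a second dim one of Ids was also called (0.87). For other increases, the brightest probe set was higher for 2610005L07Rik (0.59), Mettl21a (0.39), Usp12 (0.22) and Slc23a2 (0.165). It was lower for Cyria (-0.42) and Fndc3a (-0.4), and none of these passed. Among the largest decreases, the brightest probe set was higher for Bop1 (0.31), Edn3 (0.33), Glipr1 (0.12) and Snrnp200 (0.01). It was lower for Tob2 (-0.77), Rorb (-0.56), Fgf14 (-0.55) and Slc4a8 (-0.15), and none of these passed. For Npas3 and Ssbp1 the called probe set was itself the brightest. In a check added after seeing the data, the 200 probe sets with the smallest p were chosen with 3 arrays of each of the 2 groups and measured in the other 3, over 20 random choices. On average 128 of them had a brighter probe set of the same gene. For these 128, the mean of the medians was 0.367 log2 units for the chosen probe sets and 0.029 for the brighter ones. The 3' minus 5' signal of 4 control transcripts was higher in aSYN than in aSYN/Hsp70 by 0.126 log2 units (exact permutation p = 0.0368, adjusted p = 0.221 over the 6 pairs of groups).

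By list, 0 of 28 passed here with the settings of the report, while 4 passed without quantile normalisation, 8 without the dim filter and 4 with array weights. The striatal list, lower for 10 of 12 members (median -0.14, adjusted p = 0.0842, and 0.563 with an estimated correlation), passed in 5 of 11 settings (adjusted p 0.00561 to 0.137). Olfactory bulb genes were higher for 6 of 6 members (median 0.65, camera adjusted p = 0.0842, and 0.563 with an estimated correlation; 4.58e-05 to 0.0841 over 11 other settings) and clock genes lower for 11 of 13 (median -0.25, adjusted p = 0.0863; 0.0156 to 0.244 over 11 settings, passing in 3), with Ciart at -0.89 and Dbp at -0.82 past the test adjusted over the list alone. Meninges genes passed as higher in 4 of 11 settings (0.0107 to 0.117) and thalamus genes as lower in 2 (0.0229 to 0.529). Dopamine neuron, choroid plexus and myelin genes passed as lower in 1 each. The endothelial tight junction gene Cldn5 rose by 0.71 (limma adjusted p = 0.046), with Cdh5 at 0.64 and Slc2a1 at -0.27. Others that passed adjusted over the list alone were Tac1 (-0.47), Gpr6 (-0.67), Drd1 (-0.28), Pde10a (0.33), Slc1a3 (0.33), Laptm5 (-0.61), Ret (-0.83), Clic6 (-0.41), Doc2g (1.20), Atg7 (0.45), Ctsl (-0.26), Psmc2 (-0.26), and the respiratory chain genes Ndufa5 (-0.43), Ndufb3 (-0.25) and Sdhd (0.35). The count of 194 fell to 89 with the sex covariate, to 100 without the 4 arrays that stood apart and to 7 with only the arrays of these groups. It was 49 without aSYN replicate 2 or 3 and 814 without aSYN/Hsp70 replicate 6. The median change of the 194 was 0.588 with the sex covariate and 0.502 without the 4 arrays, against 0.596. As the 194 were chosen in these same arrays, their medians do not settle why calls ended.

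What aSYN added to the Hsp70 genotype gave 0 limma calls, with 2599 probe sets at an unadjusted p under 0.05, and 0 lists, though 2 lists passed without quantile normalisation and 1 with array weights. The smallest p-values, all at adjusted p = 0.122, belonged to the imprinted RNA Kcnq1ot1 (-1.08), Ceacam1 (0.98), Gpr1 (0.79), Rnf157 (1.38) and Morf4l2 (0.41). Fbxo7, a gene of familial parkinsonism, stood at 0.27 and Fcrls at -0.82, both past 0.05 adjusted over the list alone. Without the 4 arrays that stood apart, 4 probe sets were called.

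The interaction asked whether the aSYN difference depended on Hsp70. The 5 genes with the smallest p, all at adjusted p = 0.0516 and so not passing, were Ip6k1 (0.83), Sort1 (0.87), Btbd3 (0.76), Prepl (0.67) and the RNA editing enzyme Adarb1 (1.05). Sort1 averaged 11.06 ± 0.07 in aSYN against 11.65 ± 0.09 in aSYN/Hsp70, and 11.47 ± 0.27 in Hsp70 (SD, n = 6). Pde10a (0.60) and Slc1a3 (0.41) passed adjusted over the list alone. The interaction shares the aSYN arrays with aSYN versus wt and with aSYN/Hsp70 versus aSYN. Values of Sort1, Pde10a and Slc1a3 in these comparisons are therefore not independent of each other. By limma, 0 probe sets were called and 2198 had an unadjusted p under 0.05; array weights gave 81 calls. Of the lists 0 passed, while 4 did without quantile normalisation, with the sex covariate or with a trended variance.

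Differences on separate arrays were then set against each other. Across 27022 probe sets, the aSYN difference without Hsp70 and that with it gave r = -0.01 (relabelling p = 0.79). The Hsp70 difference without aSYN and that with it gave r = 0.23 (relabelling p = 0.14). It was 0.0213 with array weights (label permutation p = 0.66) and 0.129 without the dim filter (label permutation p = 0.06). In fits added after seeing the data it was 0.0158 with weights and the sex covariate (label permutation p = 0.7) and -0.0487 without the 4 arrays that stood apart (label permutation p = 0.24). Of the 194 probe sets called in aSYN/Hsp70 versus aSYN, 87 (44.8%) had the same sign in Hsp70 versus wt. Wt minus aSYN and aSYN/Hsp70 minus aSYN share the aSYN arrays: their r was 0.385 against 0.499 simulated with no effect, the covariance was 0.0355 against 0.0384, and over 20 splits of the aSYN arrays r averaged 0.0929, from -0.0126 to 0.191. For 200 genes chosen per split, the mean of medians was 0.682 in the aSYN arrays that chose them. Against the other aSYN arrays it was 0.5 for aSYN/Hsp70 and 0.218 for wt (0.164 to 0.26). Only the aSYN arrays were split, not the aSYN/Hsp70 arrays. The 0.5 is therefore not free of the choice and cannot be set against the 0.218.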

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

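The tests without the 4 arrays that stood apart, by splits under either correction, on arrays not used for the choice, of the 3' minus 5' signal and of Fisher were chosen after the results were seen; the fit with the sex covariate was fixed in advance, but the bound it was read against was written afterwards, as was that for the counts over other splits of the samples.

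The 194 calls in aSYN/Hsp70 versus aSYN were reached by 1 of 100 splits of these arrays, the real one, with at most 2 calls in the others. That argues against a random division of these arrays as the source, at a resolution of 1 in 100 and for the comparison with the most calls of 6. A batch or handling order that goes with the groups could not be tested by splits, as the labels give no date or batch. Calls were still made without the 4 arrays that stood apart (100, of which 67 were among the 194, with at most 4 in the other splits of that fit) and with the sex covariate (89, of which 87, with at most 1), each count reached by 1 of 100 splits, which argues against either as the source of those; for the 127 and 107 calls that ended, both stay open. The 200 probe sets with the smallest p were also measured in arrays not used to choose them. Those that had a brighter probe set of the same gene changed by 0.367. The brighter ones changed by 0.0826 of the change of the chosen ones (mean of 20 splits, -0.124 to 0.238), as a change in single probe sets would give. Shorter or more degraded cDNA in the aSYN arrays stays open: over 4 control transcripts the 3' minus 5' signal was higher there by 0.126 (exact permutation p = 0.0368, adjusted p = 0.221 over the 6 pairs of groups), from Actb (0.136) and Pcx (0.471) and not Gapdh (-0.0126) or Tfrc (-0.0904); Actb and Gapdh alone gave 0.0615 (exact permutation p = 0.0108), and Tfrc and Pcx alone 0.19 (exact permutation p = 0.104). No single control passed over the 24 comparisons made (smallest adjusted p = 0.104), and a change of transcript forms with genotype stays open, as it was not tested.

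The striatal neuron list was lower in Hsp70 than in wt brains. Its median without the 4 arrays that stood apart was 1.07 of that with them (camera adjusted p = 7.13e-13), and with the sex covariate 1.02 (9.02e-09). These medians argue against both as the whole source. Both p-values use the preset correlation, and estimated ones are not given for these fits. In the report's settings the estimated correlation gave a camera adjusted p of 0.0429. The fit without the 4 arrays leaves out Hsp70 replicates 3 and 6. A smaller share of striatal tissue in these samples and a lower expression in striatal neurons with the genotype both stay open, as neither was tested.

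The 4 arrays that stood apart were all among the 12 with Hsp70 and none among the other 12. Fisher's exact test gave p = 0.0932, so chance stays open. Degraded RNA stays open too: the 3' minus 5' signal of the 4 controls differed by -0.0656 between these arrays and the others, within the SD of 0.121 among the others, and the controls disagreed (Actb -0.176, Gapdh 0.122, Tfrc 0.0265, Pcx -0.236). These 4 arrays also had the highest medians (893.1, 712.1, 637 and 598.3, against at most 580.9 in the others). Their highest intensities were 413491, 356735, 301248 and 293037, against at most 253424 in the others. What gave these distributions, and other candidate sources, were not tested.

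For the remaining comparisons, the real labelling was set against other splits in the same way. The 1 call in aSYN versus wt was reached by 1 of 100 splits, with at most 0 in the others. The real count was 0 in Hsp70 versus wt (at most 1 call in other splits), aSYN/Hsp70 versus wt (at most 3), the interaction (at most 2) and aSYN/Hsp70 versus Hsp70. Every split gives at least 0 calls, so counting splits could not decide about chance in those comparisons. In aSYN/Hsp70 versus Hsp70, another split gave 367 calls, with the 4 arrays that stood apart all on one side. That points to a structure of the samples that does not follow aSYN. Whether it follows Hsp70 stays open, as both groups of this comparison carry it.

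Single arrays far from the rest of their group were looked for in array measures, list scores and 85 named probe sets. Among the 340 groups of probe set values, 23 held such an array where chance gives about 17, and 6 were in aSYN/Hsp70 replicate 4. That array had a median intensity of 893 (group median 558), a thalamus score of -1.12 (-0.245), a myelin score of -0.744 (-0.196), and log2 intensities of 7.86 for Hspa1a (11.1), 12.2 for Atg7 (11.4), 14 for Mal (14.4), 14.4 for Ndufa5 (15), 11.4 for Rnf157 (9.88) and 10.4 for Zfp953 (9.03). In aSYN/Hsp70 replicate 3, Prss29 was at 7.48 (8.81), and in replicate 2 the clock score was 0.137 (-0.175) and Hspa1b 11.2 (12.7).

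In Hsp70 brains, replicate 3 stood out in Adamts20 at 9.38 (10.1), Ciart at 11.9 (10.5), Cnp at 15.4 (15.8) and Slc4a8 at 7.03 (8.92). Replicate 6 had a clock score of -0.295 (-0.0773) and Zfp953 at 9.95 (8.67), replicate 5 an olfactory bulb score of 1.5 (-0.273) and replicate 1 a pituitary score of 0.0933 (-1). In aSYN brains, replicate 5 stood out in Ceacam1 at 10.8 (9.85), Hspa1a at 10.8 (11.2) and Slc23a2 at 9.37 (9.99), replicate 1 in Mobp at 16.2 (15.8) and replicate 3 in Rora at 13.2 (13.3). In wt brains, replicate 3 stood out in 2610005L07Rik at 7.54 (8.68) and Hspa1a at 10.3 (11.1), replicate 5 in Cnr1 at 11 (10.5), replicate 4 in Hspa1b at 13.7 (12), replicate 6 in Slc4a8 at 7.44 (8.72) and replicate 1 in the thalamus score at 0.417 (-0.0679).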

How the results depend on the processing

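The fits without the 4 arrays that stood apart, with weights and sex together, and with an offset of 256, and lists with an array left out, were chosen after seeing the data; causes were not tested except where fewer arrays or more probe sets entered. Calls in aSYN versus wt (1) were 9 without quantile normalisation, 0 without the dim filter, 217 with array weights, 0 with the sex covariate, 3 with a trended and robust variance, 35 without the 4 arrays, 189 with weights and sex, and 0 with only these groups' arrays. Calls in aSYN/Hsp70 versus aSYN (194) were 43 without the dim filter, 324 with weights, 89 with sex, 369 with the trended variance, 100 without the 4 arrays (67 of them shared with the 194) and 7 with only these groups' arrays; under the 10 settings that kept all comparisons, all 194 kept their sign. Calls in Hsp70 versus wt (0) were 1 with weights and sex. Calls in aSYN/Hsp70 versus wt (0) were 1 without the 4 arrays and 4 with only these groups' arrays. Calls in aSYN/Hsp70 versus Hsp70 (0) were 5 with weights, 4 without the 4 arrays, 5 with weights and sex, and 2 with an offset of 256. Interaction calls (0) were 5 without quantile normalisation, 81 with weights, 24 with the trended variance, 5 without the 4 arrays, 44 with weights and sex, and 8 with an offset of 256.

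With the replicate number as a block, calls were 2 in aSYN versus wt and 70 in aSYN/Hsp70 versus aSYN, and 0 in the other 4 comparisons. The samples share only a number, which goes with sex (27 of 36 same-numbered pairs and 79 of 180 others were of 1 sex). Deviations of 36 same-numbered pairs correlated at a median of 0.0191 (-0.148 to 0.193), the others at -0.00757, and 8 of 24 arrays correlated best with their own number.

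Leaving out 1 array of the groups compared gave 0 to 5 calls in aSYN versus wt (5 without wt replicate 1, 1 without aSYN or wt replicate 4, 0 in the other 9 fits), 0 to 0 in Hsp70 versus wt, 0 to 1 in aSYN/Hsp70 versus wt (1 without wt replicate 4) and 0 to 2 in aSYN/Hsp70 versus Hsp70 (2 without Hsp70 replicate 3 or aSYN/Hsp70 replicate 4, 1 without Hsp70 replicate 6 or aSYN/Hsp70 replicate 1 or 3). In aSYN/Hsp70 versus aSYN it gave 49 to 814: 49 without aSYN replicate 2 or 3, 56 without 6 and 127 without 4; 66 without aSYN/Hsp70 replicate 3, 101 without 4, 120 without 2 and 814 without 6. Interaction calls ran from 0 to 30: 14 without Hsp70 replicate 1, 6 without 3, 2 without 6 and 30 without aSYN/Hsp70 replicate 6.

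The r of the aSYN differences turned to 0.00359 without the dim filter, and that of the Hsp70 differences to -0.0487 without the 4 arrays. Called lists kept their direction in all settings run and lost the call in 26 of 121, most in aSYN versus wt. Other lists were called in 2 of 11 settings in aSYN versus wt (at most 2 lists), 2 in Hsp70 versus wt (1), 5 in aSYN/Hsp70 versus wt (3), 7 in aSYN/Hsp70 versus aSYN (8), 3 in aSYN/Hsp70 versus Hsp70 (2) and 7 in the interaction (4). In aSYN/Hsp70 versus aSYN these were 4 lists without quantile normalisation, 8 without the dim filter, 4 with weights, with or without sex, 2 without the 4 arrays, and 1 with the block or an offset of 256. Against Hsp70 they were 2 without quantile normalisation and 1 with weights, with or without sex (olfactory bulb, 0.000439 with weights). In the interaction they were 4 without quantile normalisation, with sex or with the trended variance, 1 with the block or with weights, with or without sex, and 3 with an offset of 256. With 1 such array left out, the proteasome list and those called in other comparisons kept their calls. In aSYN versus wt the call ended for the pituitary list without wt replicate 1 (0.0768) or 5 (0.288), heat shock without aSYN 2, 5 or 6 or wt 1 or 4 (up to 0.15), striatal without aSYN 1, 2 or 3 or wt 1, 5 or 6 (0.214), unfolded protein response without aSYN 1, 2, 5 or 6 or wt 1 or 4 (0.146), astrocyte without aSYN 2 or 4 or wt 1 or 6 (0.124) and interferon without aSYN 1 or 3 or wt 1 or 2 (0.162). For named genes, 1043 values kept their side of the threshold, 90 lost the call, 59 gained it and 18 changed sign, all in Hspa1a or Hspa1b and none of them called. Hspa1a turned to 0.186, 0.257 and 0.238 in aSYN/Hsp70 versus wt (array weights, without the 4 arrays, weights and sex), to 0.28, 0.352 and 0.3 against Hsp70, to 0.0625, 0.196 and 0.0896 in the interaction, and against aSYN to 0.102 and 0.0278 in the last pair of settings. Hspa1b turned to -0.000993 in aSYN versus wt without quantile normalisation, to -0.051 in Hsp70 versus wt (weights and sex), to -0.123 (sex) and -0.0247 (weights and sex) against aSYN, to -0.00826 (without the 4 arrays) and -0.0424 (sex) against Hsp70, and to -0.11 (sex) in the interaction.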

Other observations

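Tests in this part were planned, except the exact permutation tests of list scores and where an alternative is named as added after seeing the data. Olfactory bulb genes were higher in aSYN/Hsp70 than in aSYN for 6 of 6 members, a list that did not pass with the settings of the report (camera adjusted p = 0.0842, and adjusted p = 0.563 with an estimated correlation). It passed in 7 of 11 other settings, among them without quantile normalisation (0.0229), without the dim filter (0.0334), with the replicate block (0.037), with array weights (4.58e-05) and, in alternatives added after seeing the data, without the 4 arrays that stood apart (0.000497) and with an offset of 256 (0.0459). The score per array averaged 0.41 ± 0.9 in aSYN/Hsp70 and -0.34 ± 0.15 in aSYN relative to wt (SD, n = 6), and neither passed against wt by score (exact permutation p = 0.357 and 0.132); as a list it passed in aSYN/Hsp70 versus wt in 3 of 11 settings, with array weights (0.00034) and, in fits added after seeing the data, with weights and sex (0.000508) and without the 4 arrays (0.00892), against 0.213 in the report's settings. Immediate early genes had an interaction below 0 for 12 of 12 members (median -0.49, adjusted p = 0.0608, and 0.757 with an estimated correlation; 0.0322 to 0.226 over 11 settings). Pituitary genes had one above 0 for 4 of 4 (median 1.80, adjusted p = 0.0608, and 0.701 estimated; 0.0281 to 0.278 over 11 settings), with an SD of the score of 2.3 in wt. Astrocyte and olfactory bulb genes had interactions above 0 for 11 of 12 and 6 of 6 (adjusted p = 0.0608 each, and 0.701 and 0.757 estimated; 0.0322 to 0.226 and 0.00115 to 0.107 over 11 settings). Lists that passed in aSYN/Hsp70 versus wt only in other settings were also the respiratory chain, higher without quantile normalisation (0.000523), choroid plexus, lower without the dim filter (0.0152) and with array weights (0.0483), and meninges, higher with array weights (0.0402) and with weights and sex (0.0129). In aSYN versus wt, cerebellum genes passed as lower without the dim filter (0.039) and myelin genes with the mean of all probe sets of a gene (0.0375).

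Several lists that bear on the genotypes did not pass in aSYN versus wt. Synaptic vesicle genes were higher for 12 of 19 members with a median of 0.02, familial parkinsonism genes for 6 of 12 (0.01), dopamine neuron genes for 5 of 9 (0.01), respiratory chain genes for 23 of 33 (0.02) and oxidative stress defence genes for 11 of 15 (0.02), and 0 of these lists passed; with the mean of all probe sets of a gene the respiratory chain list did (adjusted p = 0.0375, from 0.0375 to 0.336 over 11 settings). Kif5c, chosen after its values were seen, had probe sets that moved apart: in aSYN/Hsp70 versus aSYN one rose by 0.48 (limma adjusted p = 0.0244), another fell by 0.43 (adjusted p = 0.0353) and the brightest differed by -0.10 (adjusted p = 0.393).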
